A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

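Total RNA of Saccharomyces cerevisiae grown at 4 glucose levels was read on one-colour Affymetrix arrays after extraction with Trizol LS reagent and biotin labelling by the manufacturer's protocol, per the labels. The labels give 3 arrays for each of 2%, 1%, 0.5% and 0.25% glucose, which the series design calls biological replicates; each sample title holds the word log, which the labels do not explain, and beyond it strain, growth phase and sampling time are not given in the sources used here. The deposited values are array intensities, 1 summarised signal per probe set on a linear scale, which the authors had already scaled between arrays: the mean signal, without the lowest and highest 2% of probe sets above 0, is 500 on each of the 12 arrays. The program that summarised and scaled them is not given in the sources used here. Such scaling sets the mean of each array alike, so a change in total RNA per cell cannot be seen, and a shift that depends on brightness stays in the values.

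The array holds 10928 probe sets, of which 5028 are at 0 on every array and 5900 above 0. Probe sets were paired with genes through the reference table of probe sets and gene names: 5498 were named for 1 gene of S. cerevisiae, 1747 for other genes (all of them at 0, and 1 of them with several symbols), and 3683 had no listed gene, 402 of these above 0 (184 controls and 218 others). For the 47 genes with more than 1 probe set the brightest was used, which left 5449 genes. Signals were log2 transformed with a floor of 1, and the values were used as deposited because the array medians of the tested genes lay within 0.173 of each other (limit 0.2). Genes with a mean at or below the percentile 25 of the means (a signal of 110) were left out as dim, which left 4086 genes; 1363 were not tested.

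Differences were tested with limma 3.58.1 in R 4.3.3: a mean per glucose level over all 12 arrays, a shared spread, and moderated tests with an intensity trend in the variance prior, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The contrasts were 1%, 0.5% and 0.25% against 2%, 0.5% against 1% and 0.25% against 0.5%; a moderated F-test over the 3 contrasts against 2% asked for any difference, a slope on the log2 glucose level for a trend, and an F-test of the quadratic and cubic terms for departures from it. Before the data were examined, 29 gene lists were written from textbook knowledge, of which 28 had at least 5 tested genes: hexose transporters and glucose sensors, glucose-repressed sugar and ethanol use, gluconeogenesis and glyoxylate cycle, glycolysis and fermentation, TCA cycle, respiratory chain, ATP synthase, fatty acid oxidation and peroxisome, trehalose and glycogen metabolism, general stress, antioxidant defence, ribosome biogenesis, RNA polymerases I and III, amino acid biosynthesis, sulfur and methionine metabolism, nitrogen catabolite repression, phosphate and iron regulons, ergosterol, NAD biosynthesis and sirtuins, DNA replication and histones, mitosis and daughter cell separation, stationary phase, mating, cytosolic and mitochondrial ribosomal proteins, proteasome and autophagy; sporulation had 1 tested gene. Lists were tested with limma's camera (preset correlation 0.01, adjusted over the lists), with camera under an estimated correlation, and with fry. Counts of list members are over the tested members and were made with p adjusted over all genes and over the list alone.

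Genes named in the text follow a rule set before the data were examined: for each comparison with 2% and for the trend, the 10 largest rises and 10 largest falls that passed with no overlap between the arrays of both levels (for the trend, with level means in order); for each list, up to 4 members with the largest absolute change at 0.25%; a panel of 36 genes of glucose signalling whatever their result; and for the steps and the departure test, the 5 largest rises and 5 largest falls that passed. Fewer are printed in places, in order of size. The functions of genes are background knowledge.

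The labels number the arrays of each level 1 to 3 without saying that equal numbers belong together. Pairing was checked on deviations from the level means: 17 of 18 pairs of same-numbered arrays had r above 0.1 (from -0.027 to 0.712, across genes), and 12 of 12 arrays correlated best with arrays of their own number. All 3 pairs passed for each comparison except 1% against 2%, where replicate 2 gave the lowest value. The design set before the data were examined had no block, so fits with the replicate number as a block are given beside many of the results they change. Counts of list members are from the fit without the block, and with it more members passed in some lists.

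Alternatives planned before the data were examined were quantile normalization, median scaling, an offset of 16 before the log, no dim filter or one at the median (percentile 50), the mean of a gene's probe sets, all probe sets, the replicate block, a fit of the compared levels alone, no intensity trend, array weights (whose estimation stopped before its tolerance in some fits; statmod 1.5.0), an adjusted p under 0.01, a fold change of at least 1.5 as well, each array left out in turn, and for lists an estimated correlation or fry. Added after seeing the data were the mean signal of 16 ribosomal RNA probe sets as a covariate, the trend without the 2% arrays, and the comparisons without the probe sets marked as shared between transcripts (67 of the tested genes). Control measures were the ribosomal RNA signal and the 3' to 5' signal ratio of 7 control genes; they were compared between the 2% arrays and the other 9 by exact permutation.

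The procedure was tested on simulated data made from the spread of these arrays, with 200 of 4086 genes changed in each of 20 simulations. For 0.25% against 2% it found 76.6%, 99.2% and 99.9% of genes changed by 0.5, 1 and 1.5 log2 units, with 5.53% false calls; for the trend it found 80.4%, 99.5% and 100% of genes with those changes at the lowest level, with 5.25% false calls. A list shifted by 0.3 was called in 100% of 20 simulations and other lists in 0.185%. The simulations for genes and for lists drew every gene and array independently. They lack the correlation between genes, and the deviation shared by same-numbered arrays, that the real arrays hold. The rates of found and false calls may thus not hold for the real arrays. Sharing of the 2% arrays was simulated 100 times with no effect. Splits of the arrays into other groups were counted over all 10 splits of 6 arrays, or over 100 random splits of the 12. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Precision is limited by 3 arrays per level.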

Results

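Transcript levels were measured in Saccharomyces cerevisiae, budding yeast, grown with 4 glucose concentrations: 2%, 1%, 0.5% and 0.25%. Each level had 3 biological replicates, so 12 arrays were read, each with a single biotin-labelled total RNA sample. Glucose is the preferred carbon source of this yeast, and while it is abundant the cells repress genes for the use of other carbon sources and for respiration. The comparisons ask which transcripts differ between the standard 2% level and each lower level, whether they follow the glucose level in a graded way, and where along the series they change. Of the 5449 genes with a probe set, 4086 were bright enough to be tested. The signals of the tested genes correlated with r between 0.9815 and 0.9933 for arrays of the same level, and between 0.9588 and 0.9954 for arrays of different levels (log2 scale, across genes, which are not independent replicates). The number of arrays limits the precision: the median standard error of a log2 fold change was 0.11.

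Control probe sets differed between the 2% arrays and the others. The mean log2 ratio of 3' to 5' signal over 7 control genes was 1.28 ± 0.12 (SD, n = 3) at 2% glucose, 0.88 ± 0.06 at 1%, 0.91 ± 0.03 at 0.5% and 0.88 ± 0.04 at 0.25%. The 3 arrays at 2% exceeded the other 9 by 0.40 (two-sided exact permutation p = 0.0045, the smallest that 220 splits can give). The mean log2 signal of 16 ribosomal RNA probe sets was 7.66 ± 0.98 at 2% and 8.85 ± 0.75, 9.02 ± 0.67 and 8.82 ± 0.77 at the lower levels. The 2% arrays lay below the other 9 by a difference of -1.23 (two-sided exact permutation p = 0.036).

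**Figure D1:**
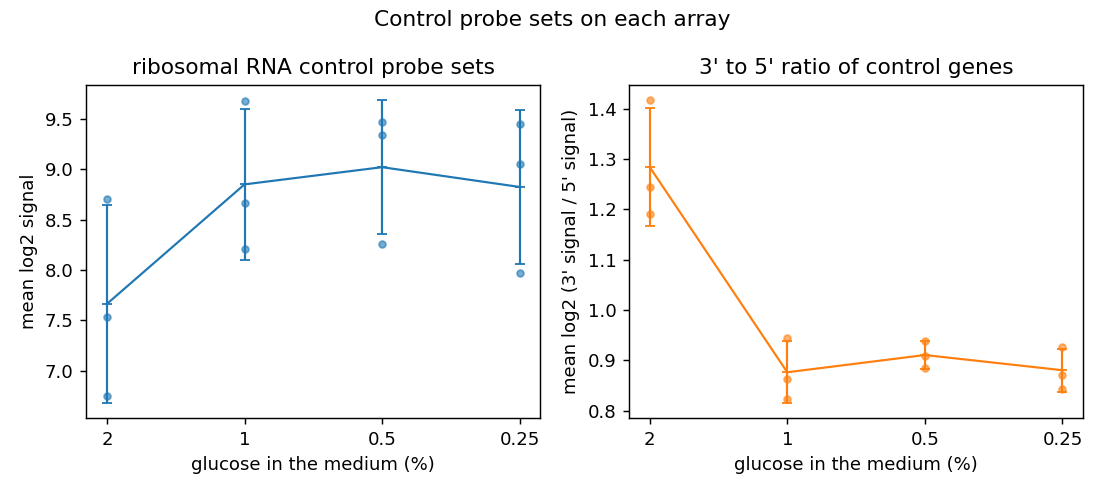
Mean log2 signal of the ribosomal RNA control probe sets (left) and mean log2 ratio of 3' to 5' signal of control genes (right) on each array, by glucose level in percent; points are arrays, lines join level means and bars are SD (n = 3). The 3' to 5' ratio lies at 1.19 or more on the 2% arrays and at 0.94 or less on all others.

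The comparison of 0.25% with 2% glucose asks what an 8-fold lower supply of glucose does to the transcriptome. HXT1, the low-affinity glucose transporter used at high glucose, fell from a signal of 1350 ± 70.0 to 59.6 ± 12.5 (SD, n = 3 each), 23.0-fold lower. HXT3, another low-affinity transporter, fell from 2353 ± 198 to 1063 ± 180. Transporters of higher affinity rose: HXT7 from 345 ± 50 to 2275 ± 38.8 (6.64-fold), HXT4 from 244 ± 28.2 to 815 ± 274 and HXT2 from 1210 ± 103 to 2848 ± 68.1. The largest rise was in TMA10, which encodes a ribosome-associated protein, from 96.6 ± 10 to 762 ± 131 (7.84-fold). HXK1, a hexokinase repressed by glucose, rose 4.91-fold to 2571 ± 163. The HXT7 probe set is of a type shared between transcripts, and HXT6, which has a nearly identical sequence, had no probe set of its own.

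**Figure D2:**
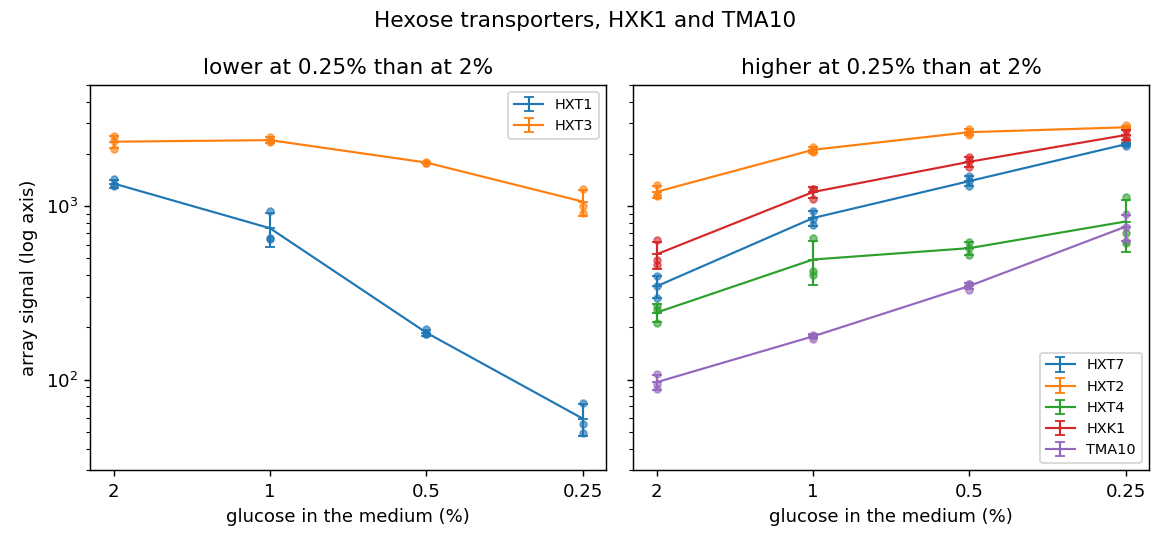
Array signal (log axis) of hexose transporters, HXK1 and TMA10 against glucose in the medium in percent; points are arrays, lines join level means and bars are SD (n = 3). HXT1 drops from 1350 at 2% to 59.6 at 0.25% while HXT7 climbs from 345 to 2275.

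In all, 165 of the 4086 tested genes differed between 0.25% and 2% glucose (limma, adjusted p under 0.05), 119 higher and 46 lower, and 30 of them by at least 2-fold (28 higher, 2 lower). Of the other largest rises, PHO89, a sodium-phosphate symporter, rose by 2.70 on the log2 scale (SE 0.14, adjusted p = 8.3e-09), DDR2, a stress-induced gene, by 2.02, and GPH1, glycogen phosphorylase, by 1.81. The Ty retrotransposon genes YBL100W-A and YBL005W-A, read by probe sets shared between many copies, rose by 1.84 and 1.73. After HXT1 and HXT3, the largest falls were in PDR12, a weak-acid exporter (-0.97, SE 0.16, adjusted p = 0.0020), ARI1, an aldehyde reductase (-0.88), ANB1, a hypoxic translation factor gene (-0.83), TIR1, a cold- and anaerobiosis-induced cell wall mannoprotein (-0.83), and AAC3, the anaerobic ADP/ATP carrier (-0.80). TPO1, a polyamine exporter (-0.77), HUG1, a DNA damage-induced gene (-0.75), and ADE17, of purine synthesis (-0.73), also fell. In each of the 165 genes the 3 arrays of one level lay wholly above the 3 of the other. Calling genes on these same arrays brings this about by itself, so it is no added evidence. Chance gives it for 10% of genes, and it held for 19.7% of all tested genes.

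Fewer genes passed without single arrays: 83 without replicate 1 at 2%, 103 without replicate 1 at 0.25% and 98 without replicate 3 at 0.25%; ARI1 missed the threshold without replicate 2 at 2% (adjusted p = 0.051). With the replicate number as a block, 445 genes passed (260 higher, 185 lower), all 165 among them. With 2 levels alone in the fit 100 passed (81 higher, 19 lower), and with ribosomal RNA signal as a covariate, chosen after seeing the data, 125 passed (96 higher, 29 lower), 102 of them among the 165. Quantile normalization gave 147 higher and 75 lower genes, array weights 129 and 80, no dim filter 182 and 55, and a dim filter at the median 78 and 50. The lower genes numbered 20, 25 and 26 in the left-out fits named first, and 27 without replicate 2 at 2% and 28 without replicate 2 at 0.25%.

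Counts of list members here are over the genes bright enough to be tested. In the list of glucose-repressed genes of sugar and ethanol use, 8 of the 25 genes with a probe set were tested, of which 7 rose and all 8 when adjusted over the list alone, led by HXK1 (log2 2.29), ALD4, mitochondrial aldehyde dehydrogenase (1.36), GUT2, mitochondrial glycerol-3-phosphate dehydrogenase (1.18), and GLK1, glucokinase (0.95). The list as a whole shifted upward (median 0.93, camera adjusted p = 6.4e-18; adjusted p = 0.048 with an estimated correlation, and 0.056 with the replicate block as well). In the respiratory chain 7 of 21 genes rose (11 adjusted over the list alone), among them NDE1, the external NADH dehydrogenase (0.93), and RIP1, the Rieske iron-sulfur protein (0.86). The list median was 0.29 (adjusted p = 2.5e-12; adjusted p = 0.092 with an estimated correlation). Of 17 ATP synthase genes 5 rose (9 adjusted over the list alone; median 0.23, adjusted p = 2.8e-09; adjusted p = 0.092 with an estimated correlation), with INH1, the ATPase inhibitor, at 1.09. ATP2 of the same list was at 0.56 and missed the threshold (adjusted p = 0.16; 0.00062 with the replicate block). Of 19 tricarboxylic acid cycle genes 6 rose (7 adjusted over the list alone; median 0.21, adjusted p = 6.0e-08; adjusted p = 0.16 with an estimated correlation), and CIT1, citrate synthase, rose by 0.65. These lists moved between arrays whose 3' to 5' ratio, higher at 2%, and ribosomal RNA signal, lower at 2%, differed as well.

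Of 14 genes of gluconeogenesis and the glyoxylate cycle with a probe set 6 were tested, and 2 of these rose (4 adjusted over the list alone): ACS1, acetyl-CoA synthetase (0.50), and ODC1, a mitochondrial oxodicarboxylate carrier (0.47). The list median was 0.39 (adjusted p = 0.00097; adjusted p = 0.092 with an estimated correlation). ACS1 was called by a narrow margin (adjusted p = 0.045) and missed the threshold without any of 9 single arrays, with adjusted p from 0.054 without replicate 1 at 1% to 0.22 without replicate 1 at 2%; ODC1 missed it without any of 5, with adjusted p up to 0.15 without replicate 1 at 2%. Both also missed it with the compared levels alone in the fit (0.099 each) and with the ribosomal RNA covariate (0.16 and 0.10), and ACS1 with quantile normalization (0.13). Glycolysis and fermentation were not called as a list (16 genes, median 0.08, adjusted p = 0.12; 0.68 with an estimated correlation). It was called higher with quantile normalization (0.043), array weights (0.0011), without replicate 3 at 2% (0.0015) and without replicate 1 at 0.25% (0.0067). TDH1, glyceraldehyde-3-phosphate dehydrogenase, was the 1 member called (0.40, adjusted p = 0.027). TDH1 missed the threshold without replicate 1 at 2% (adjusted p = 0.15), replicate 3 at 2% (0.064) or replicate 1, 2 or 3 at 0.25% (0.085, 0.070 and 0.076). Fatty acid oxidation and peroxisome genes were not called as a list, but only 5 of the 23 with a probe set were tested (0 called, median 0.03, camera adjusted p = 0.40). Among mitochondrial ribosomal protein genes 3 of 71 rose (6 adjusted over the list alone), while 70 of 71 had positive values (median 0.18, adjusted p = 5.7e-11; adjusted p = 0.26 with an estimated correlation).

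Of 21 genes of trehalose and glycogen metabolism with a probe set 14 were tested, and 6 of these rose (10 adjusted over the list alone), led by GPH1 (1.81), GLC3, the glycogen branching enzyme (1.74), GSY1, glycogen synthase (1.63), and PGM2, phosphoglucomutase (1.04). The list median was 0.52 (adjusted p = 1.4e-12; adjusted p = 0.098 with an estimated correlation). Of 23 general stress genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), with DDR2 at 2.02, HSP12, a membrane-associated small heat shock protein, at 1.24, SPI1 at 0.84 and GAD1, glutamate decarboxylase, at 0.67. That list had a median of 0.13 (adjusted p = 0.00041; adjusted p = 0.26 with an estimated correlation). Of 7 stationary phase markers 1 rose, GIS1 (0.62), and 2 when adjusted over the list alone (median 0.14, adjusted p = 0.039; adjusted p = 0.18 with an estimated correlation). The stationary phase call was lost without replicate 1 at 2% (adjusted p = 0.14), replicate 1 at 0.25% (0.087) or replicate 2 at 0.25% (0.051), with quantile normalization (0.051), median scaling (0.052) or a dim filter at the median (0.15). GIS1 missed the threshold without replicate 1 at 2% (0.17), replicate 2 at 0.5% (0.055) or replicate 1, 2 or 3 at 0.25% (0.072, 0.059 and 0.14), with the compared levels alone in the fit (0.055) and with the ribosomal RNA covariate (0.16). Antioxidant defence was not called by camera (22 genes, median 0.01, adjusted p = 0.38) but passed by fry (adjusted p = 0.023), with 2 members called: PRX1, mitochondrial peroxiredoxin (0.59), and YAP1, an oxidative stress transcription factor (0.46), whose call was lost without any of 6 single arrays (adjusted p up to 0.18 without replicate 1 at 2%), with the compared levels alone in the fit (0.087) and with the ribosomal RNA covariate (0.12). The stress and stationary phase lists were also not called with ribosomal RNA signal as a covariate (both with adjusted p = 0.15); that signal was lower at 2%.

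In the iron regulon 9 of 24 genes rose and 16 when adjusted over the list alone, with TIS11, an mRNA-destabilising regulator of iron use, at 1.54, SIT1, a siderophore transporter, at 1.11, FIT2, a cell wall mannoprotein, at 0.90 and FET3, the high-affinity iron ferroxidase, at 0.82. The list median was 0.46 (adjusted p = 1.3e-12; adjusted p = 0.18 with an estimated correlation). The call of TIS11 was lost without replicate 1 or 2 at 2% (adjusted p = 0.12 and 0.054) or replicate 1 or 3 at 0.25% (0.075 and 0.10), with the ribosomal RNA covariate (0.10) and with array weights (0.058). That of FIT2 was lost with array weights (0.059). Of 20 genes of sulfur and methionine metabolism 8 rose (9, with 1 lower, adjusted over the list alone). MET2, homoserine acetyltransferase, was at 1.08, MMP1, an S-methylmethionine permease, at 1.06, MHT1, an S-methylmethionine homocysteine methyltransferase, at 1.01 and MET16, PAPS reductase, at 0.98 (list median 0.23, adjusted p = 1.4e-07; adjusted p = 0.092 with an estimated correlation). Of 12 nitrogen catabolite-repressed genes 2 rose, the arginine catabolic genes CAR2 (0.57) and CAR1 (0.31), and 2 adjusted over the list alone (median 0.18, adjusted p = 0.0017; adjusted p = 0.26 with an estimated correlation; 0.069 with the ribosomal RNA covariate). CAR1, at an adjusted p of 0.049, missed the threshold without any of 9 single arrays (adjusted p up to 0.22 without replicate 1 at 2%). The same happened with the ribosomal RNA covariate (0.19) and with median scaling (0.13) among other settings. Phosphate genes were not called as a list (16 genes, median 0.07, adjusted p = 0.15; called with quantile normalization, 0.042, array weights, 0.021, without replicate 1 at 0.25%, 0.036, or by fry, 0.011): PHO89 rose and PHO3, an acid phosphatase, fell (-0.44), and 3 rose and 1 fell adjusted over the list alone. The call of PHO3 was lost without replicate 1 at 2% (adjusted p = 0.066) or replicate 1 at 0.25% (0.062). Of 18 genes in the list of NAD biosynthesis and sirtuins 2 rose. They were NDE1, the NADH dehydrogenase already counted in the respiratory chain list, and PNC1, nicotinamidase (0.38). SIR2, the NAD-dependent deacetylase, was at 0.05 (limma adjusted p = 0.84). The NAD list had a median of 0.10 (adjusted p = 0.032; adjusted p = 0.40 with an estimated correlation), and its call was lost without replicate 1 at 2% (adjusted p = 0.15) or replicate 3 at 0.25% (0.17) and with ribosomal RNA signal as a covariate (0.58). In this comparison too the 2% arrays carried the higher 3' to 5' ratio (1.28 against 0.88).

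Ribosome biogenesis had a median of -0.11 over 69 genes (adjusted p = 0.00043; adjusted p = 0.56 with an estimated correlation), with 1 gene called lower, NOC4 (-0.51), and 0 adjusted over the list alone (limma). NOC4 missed the threshold without replicate 1 or 2 at 2% (adjusted p = 0.15 and 0.082), replicate 2 at 0.5% (0.051) or replicate 2 or 3 at 0.25% (0.12 and 0.11) and with the ribosomal RNA covariate (0.15). The list missed it without replicate 1 at 2% (adjusted p = 0.20) and with ribosomal RNA signal as a covariate (0.96). Of 51 amino acid biosynthesis genes 5 fell (6 adjusted over the list alone), with GLT1, glutamate synthase, at -0.62. The list median was -0.05 (adjusted p = 0.0046; adjusted p = 0.41 with an estimated correlation; 0.37 without replicate 3 at 2% and 0.16 without replicate 1 at 0.25%). DNA replication and histone genes had a median of -0.06 (33 genes, 0 called by limma, adjusted p = 0.043; adjusted p = 0.15 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.062), without replicate 3 at 2% (0.12), without replicate 1 at 0.25% (0.21), with quantile normalization (0.060), array weights (0.10) or a dim filter at the median (0.17). Of 18 mating and pheromone response genes 2 rose and 2 fell, and 2 rose and 5 fell adjusted over the list alone (median -0.15, adjusted p = 0.015; adjusted p = 0.26 with an estimated correlation; 0.053 with the ribosomal RNA covariate). Its member PRM4 rose by 0.60 and AGA1, an agglutinin subunit, fell by 0.59, while KAR4, a transcription factor of the mating response, was at -0.64 without passing (adjusted p = 0.11; 0.0016 with the replicate block, 0.046 with quantile normalization). Of 19 mitosis and daughter cell separation genes 0 were called by limma, while 4 rose and 1 fell adjusted over the list alone (median 0.18, adjusted p = 0.00097; adjusted p = 0.23 with an estimated correlation). CLB2, a mitotic cyclin, was at 0.67 (adjusted p = 0.051; 0.0073 with the replicate block). It also passed with quantile normalization (adjusted p = 0.047), median scaling (0.029), array weights (0.018), no dim filter (0.048), and when any of 4 single arrays was left out. With the replicate block SWI5, DSE1 and DSE3 of the mitosis list passed as higher (limma adjusted p = 0.048, 0.032 and 0.015). Of the DNA replication list POL12 and RFA2 then passed as lower (0.016 and 0.032) and RNR2 as higher (0.021).

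Cytosolic ribosomal protein genes were not called as a list (128 genes, 0 called by limma, median 0.01, adjusted p = 0.95). The list was called higher without replicate 3 at 2% (median 0.09, adjusted p = 0.00048) and with array weights (0.08, adjusted p = 0.0031). It was called lower without replicate 2 at 2% (-0.06, adjusted p = 0.00015), without replicate 2 at 0.25% (-0.04, adjusted p = 0.048) and with the ribosomal RNA covariate (-0.07, adjusted p = 0.00089). Lists for RNA polymerases I and III (24 genes, 0 called, median -0.07, adjusted p = 0.087), ergosterol biosynthesis (24 genes, 0 called, median -0.04, adjusted p = 0.16), the proteasome (34 genes, 0 called, median -0.01, adjusted p = 0.89) and autophagy (12 genes, 0 called, 1 higher adjusted over the list alone, median 0.02, adjusted p = 0.46) were not called either. Under other settings the polymerase list was called lower (with array weights, adjusted p = 0.021, with no dim filter, 0.027, and without replicate 2 or 3 at 2%, 0.045 and 0.031, or replicate 1 at 0.25%, 0.0091). Ergosterol was called lower too (with the ribosomal RNA covariate, 0.0015, and without replicate 1 or 2 at 2%, 0.027 and 0.041, or replicate 3 at 0.25%, 0.024). Autophagy was called higher with no dim filter (0.028). The list of hexose transporters and glucose sensors, with 3 of 6 members higher and 2 lower (4 and 2 adjusted over the list alone), had a median of 0.85 (adjusted p = 0.032; adjusted p = 0.37 with an estimated correlation). That call was lost without replicate 2 at 2% (adjusted p = 0.072) or replicate 1 at 0.25% (0.074), with array weights (0.053) and with a dim filter at the median (0.096). It was also lost with no dim filter (median -0.0386, adjusted p = 0.42) and without probe sets shared between transcripts, HXT7 among them (median 0.47, adjusted p = 0.73; chosen after seeing the data). The members thus moved in both directions, and the list value depends on which of them are counted. Of the sporulation markers 1 gene was bright enough, IME1 (-0.13, adjusted p = 0.67), so they were not tested as a list.

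Altogether 19 of the 28 lists shifted between 0.25% and 2% by camera with a preset correlation, 15 upward and 4 downward, but 1 with an estimated correlation, the glucose-repressed genes. By fry, which asks whether the genes of a list move one way on balance, 16 lists passed. Of the 19, ribosome biogenesis (fry adjusted p = 0.37), amino acid biosynthesis (0.12), mitochondrial ribosomal proteins (0.076), NAD biosynthesis and mating (0.072 each) missed it, while antioxidant defence and the phosphate genes were added. Other splits of the same 6 arrays called up to 18 lists, so list calls with the preset correlation say little by themselves.

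**Figure D3:**
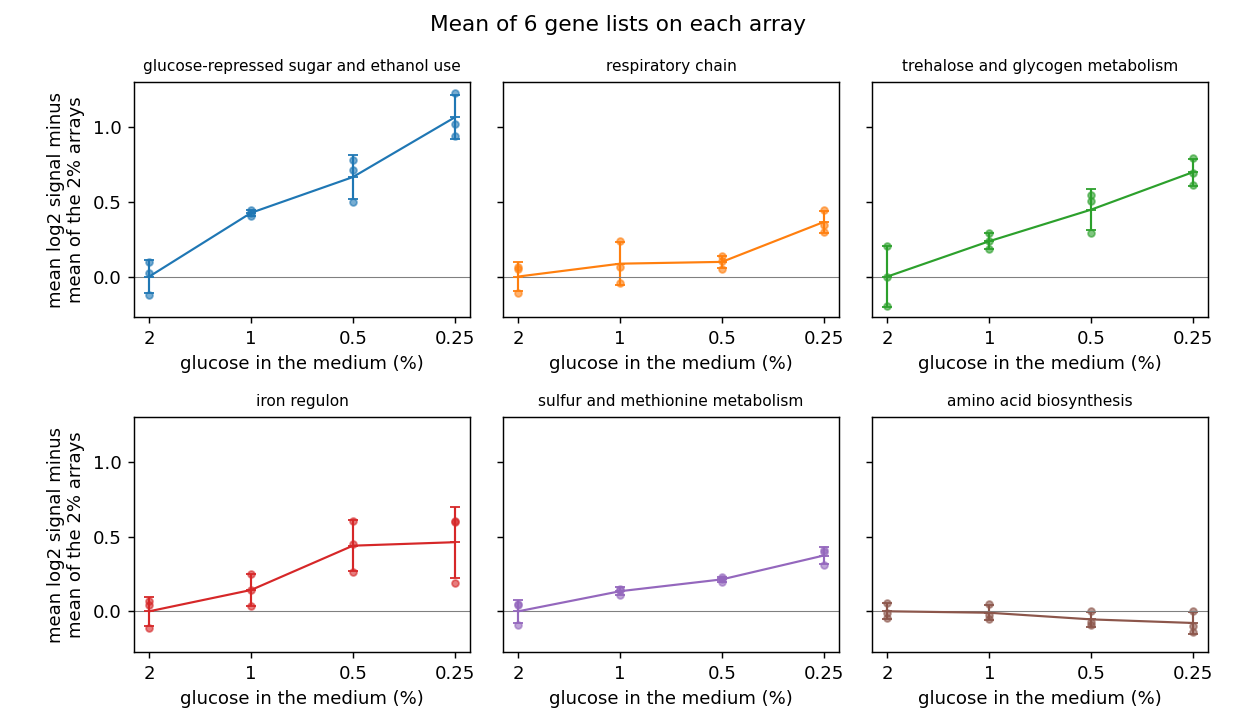
Mean log2 signal of the genes of 6 lists on each array, minus the mean of the 2% arrays, against glucose in the medium in percent; points are arrays, lines join level means and bars are SD (n = 3). The glucose-repressed, trehalose and glycogen, and sulfur lists are higher at each lower glucose level, and the amino acid list stays near 0.

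The comparison of 0.5% with 2% glucose called 47 genes (33 higher, 14 lower), 15 by at least 2-fold, and all 47 were also called in the same direction at 0.25%. HXT1 fell from 1350 ± 70.0 to 186 ± 7.27 (7.24-fold lower), PHO89 rose from 266 ± 31.1 to 1150 ± 180 (4.31-fold) and HXT7 rose to 1394 ± 90.8 (4.06-fold). TMA10 was 3.60-fold and HXK1 3.44-fold higher. HXT4 and HXT2 rose by 1.24 and 1.14 on the log2 scale, DDR2 by 1.29 and GPH1 by 1.13, and the Ty genes YBL005W-A and YBL100W-A by 1.93 and 1.61. HXT3 was at -0.40 (adjusted p = 0.075; 0.0084 with the replicate block, 0.040 with the compared levels alone, 0.011 with array weights and 0.023 without replicate 1 at 0.25%). After HXT1 the largest falls were in PDR12 (-0.72), TPO1 (-0.67), TIR1 (-0.66), ADE17 (-0.65) and AAC3 (-0.65). TIR1 and ADE17 passed without any single array, while PDR12 missed the threshold without any of 5 arrays (adjusted p up to 0.14 without replicate 2 at 2%), TPO1 without any of 3 (up to 0.075 without replicate 2 at 0.5%) and AAC3 without any of 3 (up to 0.078 without replicate 2 at 2%). With ribosomal RNA signal as a covariate PDR12 (0.099), TPO1 (0.076) and AAC3 (0.17) also missed it. So did PDR12 (0.063) and AAC3 (0.053) with the compared levels alone in the fit.

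With the replicate block 396 genes passed (137 higher, 259 lower), including the 47, so most calls there were lower while most in the fit without the block were higher. Array weights too gave more lower than higher genes (122 higher, 206 lower). Median scaling gave 69 higher and 15 lower genes, quantile normalization 67 and 24, no filter on dim genes 55 and 19, and the ribosomal RNA covariate 21 and 5. Leaving out replicate 1 at 2%, replicate 2 at 0.5% or replicate 3 at 0.5% gave 28, 23 and 28 genes, and leaving out replicate 3 at 2% gave 73 (32 higher, 41 lower). Without replicate 2 at 2% or replicate 1 at 0.5% there were 4 and 9 lower genes.

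At 0.5% the glucose-repressed genes (5 of 8 higher, 6 adjusted over the list alone; median 0.58, adjusted p = 1.5e-13; adjusted p = 0.12 with an estimated correlation), trehalose and glycogen genes (4 of 14 higher, 7 adjusted over the list alone; median 0.35, adjusted p = 5.2e-11; adjusted p = 0.27 with an estimated correlation) and iron regulon (5 of 24 higher, 13 adjusted over the list alone; median 0.38, adjusted p = 1.8e-15; adjusted p = 0.31 with an estimated correlation) shifted upward. In the iron regulon SIT1 and FET3 were at 0.99 and 0.86, and both passed. Of the respiratory chain 1 of 21 genes rose, NDE1 (0.51), with a list median of 0.03 (adjusted p = 0.0029; adjusted p = 0.43 with an estimated correlation). That call was lost without replicate 1 at 0.5% (adjusted p = 0.053), and over all settings the median ranged from -0.0455 to 0.16. Cytosolic ribosomal protein genes had a median of 0.15 over 128 genes (adjusted p = 2.8e-13; adjusted p = 0.43 with an estimated correlation), but with quantile normalization it was -0.0017. Ribosome biogenesis was the 1 list called lower (median -0.14, adjusted p = 0.00011; adjusted p = 0.54 with an estimated correlation), with NOC4 the 1 member called (-0.62), and with the ribosomal RNA covariate its median was 0.0033 (adjusted p = 0.78). It also missed the threshold without replicate 1 at 2% (0.11). NOC4 missed it without any of 4 single arrays (up to 0.13 without replicate 1 at 2%) and with the covariate (0.20). In total 16 lists were called, 15 upward, none with an estimated correlation (camera, 0 of 28) and 6 by fry, and another split of the arrays also called 16.

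Between 1% and 2% glucose 10 genes differed, 9 higher and 1 lower at 1%. The rises were in YBL005W-A (2.82-fold), PHO89 (2.77-fold), HXT7 (2.48-fold), HXK1 (2.30-fold), YBL100W-A (2.17-fold), TMA10 (1.84-fold), HXT2 (1.75-fold), GPH1 (1.67-fold) and GSC2, a glucan synthase subunit (1.49-fold), and HXT1 fell (log2 -0.88, SE 0.15, adjusted p = 0.021). In signal, HXT1 went from 1350 ± 70.0 to 746 ± 162 and HXK1 from 528 ± 93.4 to 1207 ± 87.9. HXT4 was at 0.98 without passing (adjusted p = 0.10; 0.0032 with the replicate block, 0.030 with quantile normalization, 0.015 with median scaling, 0.0089 with the ribosomal RNA covariate and 0.010 without replicate 1 at 0.25%) and HXT3 was at 0.03 (adjusted p = 0.97). Leaving out replicate 1 at 2% or replicate 2 at 1% left 6 genes called. HXT1 missed the threshold without replicate 1, 2 or 3 at 2% (adjusted p = 0.15, 0.087 and 0.058) or replicate 2 or 3 at 1% (0.18 and 0.13). It also missed it with the ribosomal RNA covariate (0.15). YBL005W-A missed it without replicate 1 or 2 at 2% (0.057 and 0.092) or replicate 2 or 3 at 1% (0.053 and 0.079). GPH1 missed it without any of 4 arrays (up to 0.15 without replicate 1 at 2%) and GSC2 without any of 6 (up to 0.20 without replicate 2 at 1%). With the compared levels alone in the fit both missed it (0.070 and 0.071), GPH1 also with the ribosomal RNA covariate (0.13) and GSC2 with no intensity trend (0.063).

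At 1% the lists with the largest median shifts among tested genes were the hexose transporters and glucose sensors (2 of 6 higher and 1 lower, 3 and 1 adjusted over the list alone; median 0.42, adjusted p = 6.7e-05; adjusted p = 0.33 with an estimated correlation) and the glucose-repressed genes (1 of 8 higher, 6 adjusted over the list alone; median 0.37, adjusted p = 1.6e-11; adjusted p = 0.17 with an estimated correlation). The transporter list had a median of -0.0147 with no dim filter (adjusted p = 0.048) and of 0.81 with the filter at the median, so its place depends on the filter. Trehalose and glycogen genes followed, with 1 of 14 higher (4 adjusted over the list alone; median 0.21, adjusted p = 3.4e-06; adjusted p = 0.48 with an estimated correlation). In total 13 lists were called, all upward, 0 with an estimated correlation by camera and 2 by fry; leaving out replicate 3 at 1% gave 7, and another split of the 6 arrays called 16. The 3' to 5' ratio differed between these arrays as well (1.28 at 2%, 0.88 at 1%).

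The 3 comparisons share the 2% arrays, which by itself makes their calls alike. Between 0.5% and 0.25%, 33 higher and 14 lower genes were shared, where independent lists of these sizes would share 0.96 and 0.16. Simulations with no effect but shared reference arrays shared 0 on average (limma, 100 simulations). With no effect hardly any gene is called, so the simulated counts here do not show how much the shared arrays add to lists of these sizes. The log2 fold changes correlated across genes with r of 0.87, against 0.50 in these simulations, and with a covariance of 0.045 against 0.0079. Between 1% and 0.5%, all 9 higher genes and the 1 lower gene, HXT1, were shared (0.073 and 0.0034 for independent lists, 0.02 in the simulations; r of 0.80 against 0.50; covariance 0.025 against 0.0079). The same 10 genes were called at 0.25% (0.26 and 0.011 for independent lists, 0.01 in the simulations; r of 0.75 against 0.50; covariance 0.028 against 0.0079). The simulations hold the sharing of the 2% arrays but no difference in their quality, such as that in the 3' to 5' ratio. They also hold no correlation between genes, so they do not show how far r could rise above 0.50 with no effect of glucose. With 3 arrays the reference could not be divided into separate groups of a pair or more each.

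Across all 4 levels, 212 genes had a slope over the log2 of the glucose level, 144 rising and 68 falling as glucose was halved. A slope does not show that the change was straight. TMA10 rose by 0.99 per halving (SE 0.04, adjusted p = 4.1e-11), HXT7 by 0.89, PHO89 by 0.87, HXK1 by 0.75 and DDR2 by 0.68, while HXT1 fell by 1.55 (adjusted p = 3.2e-10), PDR12 by 0.35, ARI1 by 0.30 and TIR1 by 0.29. Of the 212 genes, 177 had level means in strict order, a number that choosing genes by their slope over the same means raises by itself, and 161 were also called between 0.25% and 2%. No departure from a straight trend was detected among the 4086 genes (limma, 0 genes called, 82 at unadjusted p under 0.05). There were 4 with the replicate block and 2 with array weights, and 1 passed without replicate 3 at 2% or without replicate 1 at 0.25%. The simulated changes were all straight, so the power of this test to find curved ones is not known. Over the 1%, 0.5% and 0.25% arrays alone, a test chosen after seeing the 3' to 5' ratios of the 2% arrays, 40 genes followed a trend (33 rising, 7 falling). These 9 arrays also enter the trend over all levels, so that the 40 are among the 212 is no independent evidence. The moderated F-test found 87 genes that differed among the levels. The replicate block gave 434 trend genes (245 rising, 189 falling) and 332 genes by the F-test. Without replicate 1 at 2% the counts were 129 and 55. The 68 falling trend genes were 117 with quantile normalization, 42 with the ribosomal RNA covariate, 40, 39 and 45 without replicate 1, 2 or 3 at 2%, and 43 without replicate 3 at 0.25%.

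The comparison of 1% with 2% glucose, given above, called 10 genes, more than either step between the lower levels. The 3' to 5' ratio also changed there (1.28 at 2%, 0.88 at 1%). The steps between the lower levels were as follows. From 1% to 0.5%, 4 genes changed: HXT1 fell (-1.98, SE 0.15, adjusted p = 1.2e-05) and TMA10 (0.96), HXT7 (0.71) and ALD4 (0.53) rose. From 0.5% to 0.25%, 5 genes changed: HXT1 (-1.67, SE 0.15, adjusted p = 0.00011) and HXT3 (-0.76, adjusted p = 0.0045) fell, and TMA10 (1.12), HXT7 (0.71) and GSY1 (0.65) rose. HXT3 was at -0.43 from 1% to 0.5% (adjusted p = 0.26; 0.027 with the replicate block). Quantile normalization gave 7 higher and 1 lower in the first of these steps and 9 higher and 2 lower in the other, and the replicate block 18 (10 higher, 8 lower) and 17 genes (15 higher, 2 lower). In the first step 2 genes remained called without replicate 2 at 1%, replicate 2 at 0.5% or replicate 3 at 0.5%. In the other step 3 genes were called without replicate 1 or 3 at 0.5%, and 8 without replicate 1 at 2%. HXT7 missed the threshold in the first step without replicate 2 or 3 at 1% (adjusted p = 0.084 and 0.050) or replicate 2 or 3 at 0.5% (0.11 and 0.065), and in the other without replicate 1 or 3 at 0.5% (0.067 and 0.051). ALD4 missed it without any of 5 arrays (up to 0.18 without replicate 2 at 1%) and with no intensity trend (0.057). GSY1 did so without any of 9 (up to 0.27 without replicate 1 at 0.5%) and with the compared levels alone in the fit (0.051).

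By list, the step from 1% to 0.5% was led by the iron regulon (median 0.25 over 24 genes, adjusted p = 1.8e-18; adjusted p = 0.29 with an estimated correlation; 0 genes called, 8 adjusted over the list alone), and ribosome biogenesis was lower (median -0.12, adjusted p = 1.9e-06; adjusted p = 0.70 with an estimated correlation). The step from 0.5% to 0.25% was led in median by the glucose-repressed genes (median 0.38, adjusted p = 1.1e-13; adjusted p = 0.10 with an estimated correlation; 0 called, 6 adjusted over the list alone) and the respiratory chain (median 0.24, adjusted p = 1.7e-15; adjusted p = 0.10 with an estimated correlation, 0.035 with the replicate block as well; 0 called, 6 adjusted over the list alone). Cytosolic ribosomal protein genes were lower in that step (median -0.14, adjusted p = 1.5e-33; adjusted p = 0.33 with an estimated correlation; 0 called), and at -0.0055 with quantile normalization. There were 10 lists called in the first step and 12 in the other, 0 in each with an estimated correlation by camera and 0 and 1 by fry. With the replicate block and an estimated correlation, the respiratory chain and amino acid biosynthesis (adjusted p = 0.049; 0.44 without the block) passed from 0.5% to 0.25%. Other splits of the arrays called up to 16 and 15. Without replicate 1 at 0.25%, 19 lists were called in the step from 0.5% to 0.25%.

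A panel of 36 regulators and targets of glucose signalling was set before the data were examined; 35 had a probe set and 21 were bright enough to be tested. At 0.25% against 2%, SUC2, invertase, rose by 0.82 (SE 0.17, adjusted p = 0.011), but missed the threshold without replicate 1 at 2% (adjusted p = 0.070), without replicate 3 at 0.25% (0.052) and with the ribosomal RNA covariate (0.060). HXK2, the main hexokinase at high glucose, was at 0.09 (signal 3511 ± 295 at 2% and 3728 ± 222 at 0.25%, adjusted p = 0.76). MIG1, the glucose repressor, was at 0.21, SNF1, the kinase that opposes it, at -0.03, REG1, a phosphatase subunit of the same pathway, at 0.26, MSN2, a stress transcription factor, at -0.01 and the sensor regulator STD1 at -0.35, none of them called. STD1 passed with quantile normalization (adjusted p = 0.019) or median scaling (0.044). MIG2, a relative of MIG1, was at -0.68 (adjusted p = 0.20), the glucose sensor gene SNF3 at 0.47 (0.059) and CYC1, cytochrome c, at 0.32 (0.10); with the replicate block these had adjusted p of 0.00077, 0.0063 and 0.0063. SNF3 also passed with median scaling (0.026), no intensity trend (0.046), without replicate 2 at 0.25% (0.031) and, barely, without replicate 1 at 1% (0.050), and CYC1 with the ribosomal RNA covariate (0.049).

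Several regulators of the panel lay under the brightness filter and were tested only with the filter removed. MTH1, a corepressor of hexose transporter genes, went from a signal of 46.1 ± 6.92 at 2% to 202 ± 66.5 at 0.25% (log2 2.09, adjusted p = 6.2e-05). ADR1, an activator of genes for ethanol and fatty acid use, went from 45.0 ± 7.75 to 170 ± 34.8 (1.91, adjusted p = 4.6e-06), and CAT8, an activator of gluconeogenic genes, from 19.0 ± 7.66 to 54.1 ± 4.13 (1.58, adjusted p = 0.00087). HAP4, the activating subunit of the HAP complex of respiratory genes, rose by 1.07 (adjusted p = 0.0036) and MSN4, a stress transcription factor, by 1.07 (adjusted p = 0.015). MIG3, a relative of MIG1, fell from 116 ± 18.1 to 27.6 ± 8.32 (-2.10, adjusted p = 0.00011). ADH2, the ethanol-consuming alcohol dehydrogenase (0.58, adjusted p = 0.084), HXT5 (0.92, adjusted p = 0.12), SIP4 (1.00, adjusted p = 0.34), FBP1 (0.61, adjusted p = 0.65), PCK1 (0.28, adjusted p = 0.62), ICL1 (0.06, adjusted p = 0.93), CTT1 (-0.16, adjusted p = 0.80) and RGT2 (-0.04, adjusted p = 0.92) did not pass. With 16 added to every signal before taking logs, the values of ADR1, CAT8, MIG3 and SIP4 were 1.60, 1.02, -1.61 and 0.22.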

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

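Of the tests in this part, that of the numbering, that of its relation to the ribosomal RNA signal, its repeat without that signal, the permutation of whole replicate numbers, and the bound on the correlation with the 3' to 5' ratio were chosen after the result was seen. Among 132 tested probe sets without a listed gene, the probe set 1779784_at was higher at both 0.5% and 0.25% than at 2%: 605 ± 90.6 at 0.5% and 378 ± 71.8 at 2% (SD, n = 3; log2 0.69, limma adjusted p = 0.033), and 751 ± 90.9 at 0.25% (log2 1.00, limma adjusted p = 0.00086). Of the others, 3 were called lower at 0.5% and 2 at 0.25% (limma).

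The calls against 2% glucose were made against the arrays with the highest 3' to 5' ratio and, on average, the lowest ribosomal RNA signal. If the 3' bias of the 2% arrays were the whole source, the called genes would share no direction between other arrays. Of the 165 genes called at 0.25%, 92.1% (152 genes, 95% exact binomial interval 86.9 to 95.7) had the same sign between 0.5% and 1%. Of the 47 called at 0.5%, 100% (interval 92.5 to 100) had the same sign between 0.25% and 1%. The intervals count genes as independent, which genes read on the same arrays are not, so they are too narrow. With ribosomal RNA signal as a covariate the median size of the 165 fold changes went from 0.60 to 0.57 (a ratio of 0.956), all signs were kept, and 102 genes still passed while the median standard error went from 0.112 to 0.127. Both argue against these measures as the whole source; a part in single genes stays open, and the glucose level itself remains a candidate explanation not told apart from other differences between the cultures.

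Arrays with the same number deviated together from their level means, with a mean correlation across genes of 0.402, and 1 of the 216 ways to match the numbers gave a value as high (a share of 0.00463, the smallest possible; highest other 0.301), which argues against chance numbering. The main axis of these deviations, 45.9% of the variance within levels, went with the ribosomal RNA signal (r = 0.728, exact permutation p = 0.0409 over 1296 permutations, 0.0818 adjusted over the 2 measures tried; rho = 0.72, exact permutation p = 0.0471; r = 0.617 without the 2 farthest arrays), and within levels r was 0.991 at 2%, 0.605 at 1%, -0.0364 at 0.5% and 0.955 at 0.25%, from 3 arrays each. Those permutations treat the levels as independent, which same-numbered arrays are not: with the numbers moved together over all levels, 2 of 6 permutations gave as large an r (a share of 0.333, where 0.167 is the smallest possible). Removing the signal left a mean correlation of 0.127, which 17 of 216 numberings reached, but removing any measure that goes with that axis would lower it, so RNA composition or a shared handling day may or may not be behind the pairing. For the 3' to 5' ratio the exact permutation p was 0.419 (r = -0.335, rho = -0.35, exact permutation p = 0.402; r = 0.0888 without the 2 farthest arrays), which leaves that ratio open: a p of 0.05 or more had been set as evidence against it, but it does not exclude it, since with 12 arrays a correlation of a size up to 0.817 remains within the interval.

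Cytosolic ribosomal protein genes were higher at 0.5% than at 2% (median 0.152) and lower at 0.25% than at 0.5% (-0.138). As many genes of other function matched on brightness had medians of 0.123 and -0.107, and with quantile normalization the ribosomal protein medians were -0.00169 and -0.00546. The matched genes go with a scaling effect that depends on brightness, in a test that would have shown otherwise had they stayed near the median of all genes (-0.0483 and 0.038). Quantile normalization sets the brightest signals of all arrays alike, so its medians near 0 would also follow a true change. Glycolysis and fermentation genes (list medians 0.198 and -0.136) were not kept out of the matching. A change shared by bright genes is thus not told apart from scaling. A difference in ribosomal protein transcripts of the remaining size was not tested.

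Other splits of the arrays were counted for each result. For 1% against 2%, 2 of 10 splits gave at least the real 10 genes; the highest other gave 321, with replicate 1 at 1% and replicates 1 and 2 at 2% on one side, which points to a structure of the samples, and splits that part as many same-numbered pairs gave 0. For 0.5% against 2% and 0.25% against 2%, 1 of 10 splits gave at least the real 47 and 165 genes (highest others 1 and 0; 0 and 0 where as many pairs were parted). For the steps from 1% to 0.5% and from 0.5% to 0.25%, 1 of 10 gave at least the real 4 and 5 genes (highest other 0 in each). Of lists, 3, 2, 1, 4 and 4 of 10 splits gave at least the real 13, 16, 19, 10 and 12, in the same order of comparisons, with highest others of 16, 16, 18, 16 and 15, and of 5, 14, 14, 11 and 12 among splits that part as many pairs. The other splits leave some same-numbered arrays on one side, so the deviation shared by a number adds to their difference. With 10 splits there are too few for a share under 0.05. Over 100 splits of the 12 arrays, the real one and random ones, 3 gave at least the real 87 genes by the F-test (highest other 787) and 2 the real 212 trend genes (highest other 371), shares under 0.05; for departures from a straight trend 100 of 100 gave at least the real 0 (highest other 866). The split with 787 genes by the F-test, several times the real count, is also the one with 866 departing genes and points to a structure of the samples.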

How the results depend on the processing

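The ribosomal RNA covariate, the trend without the 2% arrays and the fits without shared probe sets were chosen after seeing the data; the other alternatives were set before. Over all named genes, 5899 of the recomputed values were counted as unchanged. For tested genes this means the same side of the threshold, and the same direction where called (values not called could change sign). For genes under the dim filter, which have no test, it means a change of less than their SD, and 14 values changed by more. Of the tested values 229 lost the call, 91 gained it, and 0 changed sign against a call. For called lists 1603 values kept the call and the direction and 249 lost the call; 95 values of other lists gained one, and 21 of either kind changed direction. An offset of 16, the mean of a gene's probe sets, all probe sets and no intensity trend left every total within 1.5 times that of the fit used for the results, as did no shared probe sets for the 3 comparisons with 2% (genes and lists), where alone it was run. Where a count changed, the cause was not tested, except that stricter thresholds call fewer genes by construction. Dim signals limit what can be seen: 1363 genes lay under the filter.

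The replicate number as a block, which pairs same-numbered arrays, gave 40 genes for 1% against 2% (main 10), 396 for 0.5% against 2% (47), 445 for 0.25% against 2% (165), 18 for 0.5% against 1% (4), 17 for 0.25% against 0.5% (5), 332 by the F-test (87), 434 with a trend (212) and 4 departing from it (0; 82 at unadjusted p under 0.05, limma); list counts stayed within 1.5 times. No named gene lost its call with the block. Of lists, mitochondrial ribosomal proteins (1% against 2%, adjusted p = 0.062) and DNA replication (0.25% against 2%, 0.062) lost theirs, and phosphate (1% against 2%, 0.048), TCA cycle and RNA polymerases I and III (0.5% against 1%, 0.037 and 0.031) and nitrogen genes (0.25% against 0.5%, 0.044) gained one; the block changed no other list call by camera with the preset correlation. With an estimated correlation the block ended the call of the glucose-repressed genes (0.25% against 2%, 0.048 to 0.056) and gave calls of the respiratory chain (0.10 to 0.035) and amino acid biosynthesis (0.44 to 0.049) for 0.25% against 0.5%. Array weights gave 328, 29, 22, 184 and 2 for 0.5% against 2%, 0.5% against 1%, 0.25% against 0.5%, the F-test and the departures. Quantile normalization gave 91, 8 and 11 for 0.5% against 2% and both steps, and 6 lists (main 10) for 0.5% against 1%; median scaling gave 84 and 9 for 0.5% against 2% and 0.5% against 1%. At 0.5% against 2%, calls were 70.2% higher as deposited and 82.1% with median scaling (69 higher, 15 lower); for 0.5% against 1% the share went from 75% to 87.5% (7 and 1) and for 0.25% against 0.5% from 60% to 81.8% (9 and 2) with quantile normalization. No dim filter gave 74 and the ribosomal RNA covariate 26 for 0.5% against 2%; a dim filter at the median gave 56 by the F-test; fits of the compared levels alone gave 100 for 0.25% against 2% and 7 for 0.5% against 1%. The trend without the 2% arrays had 40 genes. An adjusted p under 0.01 gave 6, 23 and 79 for 1%, 0.5% and 0.25% against 2%, 47 by the F-test and 102 with a trend; a fold change of at least 1.5 gave 90 for 0.25% against 2% and 87 for the trend. With an estimated correlation camera called 0, 0, 1, 0 and 0 lists (main 13, 16, 19, 10 and 12, for the 3 comparisons with 2% and both steps), and fry 2, 6, 0 and 1 for all but 0.25% against 2%, where it called 16.

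Leaving out each array in turn gave 6 to 13 genes for 1% against 2%, 23 to 73 for 0.5% against 2%, 83 to 183 for 0.25% against 2%, 2 to 6 for 0.5% against 1%, 3 to 8 for 0.25% against 0.5%, 55 to 92 by the F-test, 129 to 219 with a trend and 0 to 1 departing. Lists ranged over 7 to 14, 12 to 16, 17 to 21, 8 to 13 and 10 to 19. The lowest gene counts for 1% and 0.25% against 2%, the F-test and the trend came without replicate 1 at 2%, for 1% against 2% also without replicate 2 at 1%.

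Medians of lists whose direction by camera changed were as follows. With the ribosomal RNA covariate, at 1% against 2%, glycolysis was at -0.0285, general stress at -0.0483, cytosolic ribosomal proteins at -0.0226, ribosome biogenesis at 0.093, RNA polymerases I and III at 0.101 and ergosterol at -0.0649, and at 0.5% against 2% ribosome biogenesis at 0.0033. Cytosolic ribosomal proteins were at -0.0267 and -0.0198 (1% against 2%, without replicate 2 at 2% or at 1%), -0.00169 (0.5% against 2%, quantile normalization), 0.0804 and 0.0914 (0.25% against 2%, array weights or without replicate 3 at 2%), and -0.0098, -0.00325 and -0.0384 (0.5% against 1%; quantile normalization, array weights, without replicate 1 at 1%). Mitochondrial ribosomal proteins were at -0.0601 (1% against 2%, without replicate 1 at 1%). Glycolysis was at 0.00249 and -0.0262 (0.5% against 1%, array weights or without replicate 1 at 1%) and -0.00721 (0.25% against 0.5%, quantile normalization). From 0.5% to 0.25%, ribosome biogenesis was at -0.0353 without replicate 1 at 0.25% and the iron regulon at 0.146 without replicate 2 at 0.25%. Over single arrays left out, the other ends of these ranges were 0.179 without replicate 1 at 1% (cytosolic ribosomal proteins) and 0.0953 without replicate 3 at 1% (mitochondrial ribosomal proteins) for 1% against 2%, -0.0632 without replicate 2 at 2% (cytosolic ribosomal proteins, 0.25% against 2%), 0.199 and 0.166 without replicate 2 at 1% (glycolysis, cytosolic ribosomal proteins; 0.5% against 1%) and -0.0536 without replicate 1 at 0.5% (iron regulon, 0.25% against 0.5%). The cause was not tested.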

Other observations

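The test of glucose exhaustion was chosen after the result was seen, as was the reading of the oxygen-repressed genes by the gap between medians; their test by camera was set before. Genes known to be induced without oxygen stood among the falls at 0.25% against 2%. Besides ANB1, TIR1 and AAC3, TIR3, another cell wall mannoprotein, fell by 0.69 on the log2 scale (limma adjusted p = 0.0089). HEM13, of heme synthesis, fell by 0.37 (limma adjusted p = 0.023), while COX5B was at 0.07 and was not called. ROX1, a repressor of such genes and not one of them, was at -0.14 and was not called. TIR3, HEM13, COX5B and ROX1 were chosen after their values were seen.

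A hypothesis from these falls was that oxygen-repressed genes as a group were lower at 0.25%. Of 13 further such genes listed before their values were looked at, 9 were bright enough. Their median was -0.0786 (SD 0.252, from -0.376 to 0.422), with 0 called in limma and a camera p of 0.383 (0.392 with an estimated correlation). HMG2, among the 9 (-0.19), also falls under the naming rule for the ergosterol list, so its value may have been seen. ANB1, TIR1, AAC3 and TIR3, without HEM13, had a median of -0.813, more than 2 SD away from that of the 9. That comparison was added after the camera p, which by itself does not show absence, had been seen. Those 4 genes were picked because they fell, so a gap to genes not picked that way is built in. None of the 9 lay below -0.376, so falls as large as that median were not seen among them. A smaller change of the group, or one limited to a subset, could be neither shown nor excluded.

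A further hypothesis was that glucose had run out in the 0.25% cultures, which would raise the gluconeogenic and glyoxylate genes far above their 2% level. The largest fold of FBP1, PCK1, ICL1 and MLS1 was 1.53, for FBP1 (signals of 6.32 ± 2.00 at 2% and 9.59 ± 2.71 at 0.25%, SD, n = 3), and no array read above 42.6 for any of them. All 4 lay under the brightness filter and no array here shows that their probe sets respond, so exhaustion could be neither shown nor excluded with them, and the word log in the sample titles, unexplained there, was not used to settle it.

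Some genes that laboratory strains often lack or express by mating type had the following signals over the 12 arrays, given as values. URA3 read 0.22 to 6.56, LEU2 1.84 to 23.2, MET17 0.165 to 9.47, HIS3 1080 to 1410 and LYS2 445 to 606. Of mating-type specific genes, MFA1 read 1010 to 1970, STE2 1900 to 2450, MF(ALPHA)1 0.873 to 9.74 and STE3 24.9 to 42.6. Over 17 tag control probe sets the median signal was 1.03 and the highest 8.94.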
